A study of Homo sapiens with 15 samples.

How the data were processed

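Total RNA from HEK293T cells, a line derived from human embryonic kidney, was measured on 15 Affymetrix whole-transcript arrays. Per the labels' protocols, cells were transfected with siRNA, treated 48 hours later with actinomycin D at 1 ug per mL for 4 hours, and harvested. Actinomycin D blocks transcription, so that mRNA remaining after it reflects both its level before treatment and its decay. Groups and replicate numbers were taken from the sample labels. There were 5 groups of 3 arrays: LOC550643 siRNA (a pool of 4), Dcp2 siRNA, DcpS siRNA, GAPDH siRNA and a non-silencing siRNA. Nothing in the labels says whether the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

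The deposited values were probe set summaries on a log2 scale. The base was inferred from their range, since the labels do not state it. Per the submitters' processing notes, RMA (background correction, quantile normalization and probe summarization) and the oligo package were used. Quantile normalization gives the arrays like distributions, so the values show relative levels and cannot show a shift of all transcripts. The balance of higher and lower calls is to be read with this limit. The versions of RMA and oligo, the probe set definition and the array's genome build were not given in the sources used here. The array medians over all probe sets lay between 4.01 and 4.08 log2 units. No detection calls or background values were used, and the number of arrays limits the precision. No pair of arrays held identical values. The correlation between arrays of a group over all probe sets lay between 0.983 and 0.991, and that between arrays of different groups between 0.981 and 0.991.

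Of 53617 probe sets, 16098 were paired with 1 gene symbol in the platform table used here, 0 with several, and 37519 were unnamed here. The unnamed probe sets were left out of the tests of genes and were tested only as a separate set. For the 779 genes with more than 1 named probe set, the one with the highest mean over all arrays was used, which left 14884 genes. LOC550643 and DCPS had no named probe set, so the knockdown of both is not analysed here. Coordinates were not used.

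Log2 values were fitted with limma 3.58.1 in R 4.3.3 (data.table version 1.17.8; figures with matplotlib). All 15 arrays entered a linear model with 1 mean per group, so that all groups shared an estimate of the spread with 10 residual degrees of freedom. Each siRNA was contrasted with non-silencing, and LOC550643 with each of the other 3 siRNAs. P-values came from limma's moderated test, were two-sided, and were adjusted by the Benjamini-Hochberg method over the 14884 genes within a contrast. Genes with an adjusted p under 0.05 are those called changed. A moderated F test over the contrasts with non-silencing gave the genes differing among the groups. Fold changes are differences of group means in log2 units, given with the model's standard error (SE).

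Gene lists, 30 in number, covered RNA decay, stress responses, the cell cycle, metabolism and markers of other cell types. They were tested with limma's camera, two-sided, with the correlation between genes estimated for each list. The 27 lists with at least 5 measured members were tested, and 3 lists with fewer were not. Many lists were only partly measured, as the member counts given with each show. Camera with a preset correlation of 0.01 was an alternative. Lists, contrasts and tests were fixed before the data were examined. A rule chose the genes named here. It named the targeted genes in every comparison. It named the 10 largest changes in each direction against non-silencing, and the 5 largest in each direct comparison, among called genes whose 3 arrays all lay on one side of the 3 comparison arrays. It added up to 4 called members of each list. Small RNAs and olfactory receptors were left out of the largest changes. A gene named outside the rule is said to be so.

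Correlations of effects that share the non-silencing arrays were set beside 1000 simulations of unchanged groups sharing controls, and overlaps of calls beside the number that independent lists would share. The non-silencing arrays could not be split into parts of 2. The fit was tested on simulated data with the spread of the real arrays for LOC550643 against non-silencing over 14884 genes. It recovered 93.4% of genes changed by 1 log2 unit and 53.8% of those changed by 0.5, and 5.52% of its calls were false. In the same simulation camera called 0 lists without a change and 1 list when 1 list was shifted by 0.5 log2 units. The simulated genes varied independently, whereas real list members were correlated, at an estimated 0.201 for decapping and P-body genes. These results, camera's above all, therefore do not carry over to correlated genes.

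The alternatives were a block for replicate number, quantile normalization, median centring, a filter on dim genes, other rules for several probe sets, limma's trend with robust moderation, fits of the compared groups alone, and leaving out each array. The groups share replicate numbers, which the labels do not explain. Between DcpS and non-silencing the deviations of all 3 same-numbered pairs of arrays from their group means correlated above 0.1 (r = 0.613, 0.261 and 0.295), so by the rule used here these 2 groups count as paired, from the data and not from the labels. In each of the other 6 comparisons at least 1 of the 3 pairs did not. Several things were added after the data had been seen. One was an axis score, the leading principal component of the deviations of arrays from their group means over the 7442 genes above the median level. Each array was scored with its full values, so differences between groups enter the score. As a covariate it therefore also removes part of any siRNA effect along the axis. Another was a count of genes set apart in 1 direction from all 4 other groups. The others were a wider set of zinc finger genes, taken by symbol, counts of list members when arrays were left out, and the tests in which arrays were held out.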

Results

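The series measured transcript levels in HEK293T cells in which LOC550643, Dcp2, DcpS or GAPDH was targeted by siRNA. LOC550643 encodes NoBody, a small protein of P-bodies, the cytoplasmic granules that hold mRNA decapping factors. Dcp2 is the decapping enzyme of mRNA decay and served as the functionally related comparison. DcpS, which degrades the cap left after decay, and GAPDH, a glycolytic enzyme, served as unrelated comparisons. A non-silencing siRNA was the reference. Each group had 3 arrays, and all cells had received actinomycin D for 4 hours.

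The targeted transcripts were examined first. DCP2 was at 6.34 ± 0.10 log2 units in the Dcp2 siRNA arrays and 8.14 ± 0.13 in the non-silencing arrays (SD, n = 3 each), which left 28.7% of the reference level (log2 change -1.80, SE 0.13, limma adjusted p = 3.15e-06). GAPDH was at 5.97 ± 0.24 in the GAPDH siRNA arrays and 7.20 ± 0.10 in the reference (SD, n = 3 each), which left 42.6% (log2 change -1.23, SE 0.11, limma adjusted p = 2.71e-05). DCP2 was also lower in the DcpS siRNA arrays, at 7.60 ± 0.27 (SD, n = 3), a log2 change of -0.54 (limma adjusted p = 0.0252) that missed the threshold without DcpS replicate 1 or 2 or non-silencing replicate 2 or 3. Its log2 change with LOC550643 siRNA was 0.40, with a limma adjusted p of 0.148, past the threshold in none of 15 alternative settings. LOC550643 and DCPS had no named probe set, so whether their siRNAs lowered them is not analysed here.

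**Figure D1:**
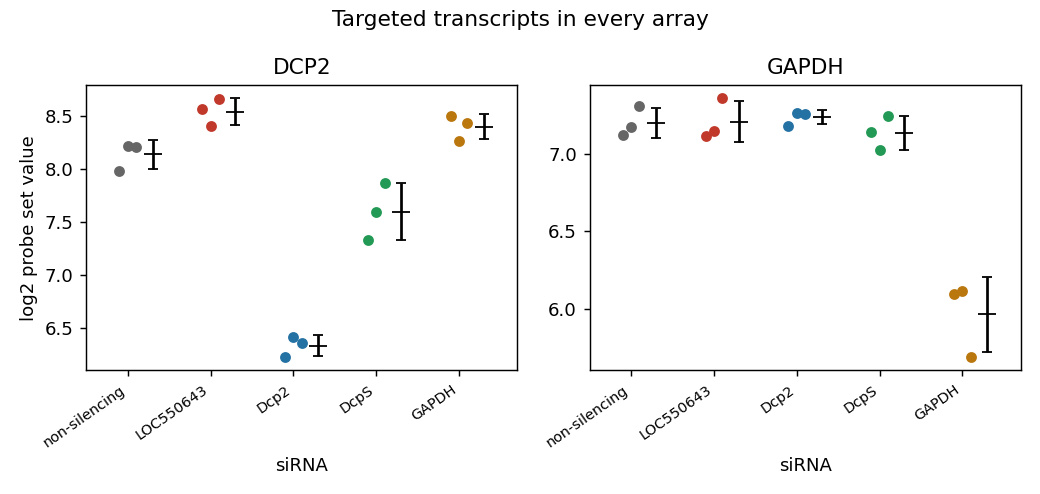
Log2 probe set values of DCP2 and GAPDH (vertical axes) by siRNA (horizontal axes); dots are single arrays and black bars the mean ± SD of 3. The Dcp2 arrays averaged 6.34 for DCP2 and the GAPDH arrays 5.97 for GAPDH, below every array of the other groups in each panel.

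Across the groups, 1815 of 14884 genes differed in limma's moderated F test. Of the genes called in single comparisons with non-silencing, 916 were called with 1 siRNA, 155 with 2, 24 with 3 and 16 with all 4. Of those called with all 4, 15 were higher than the reference with every siRNA.

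**Figure D2:**
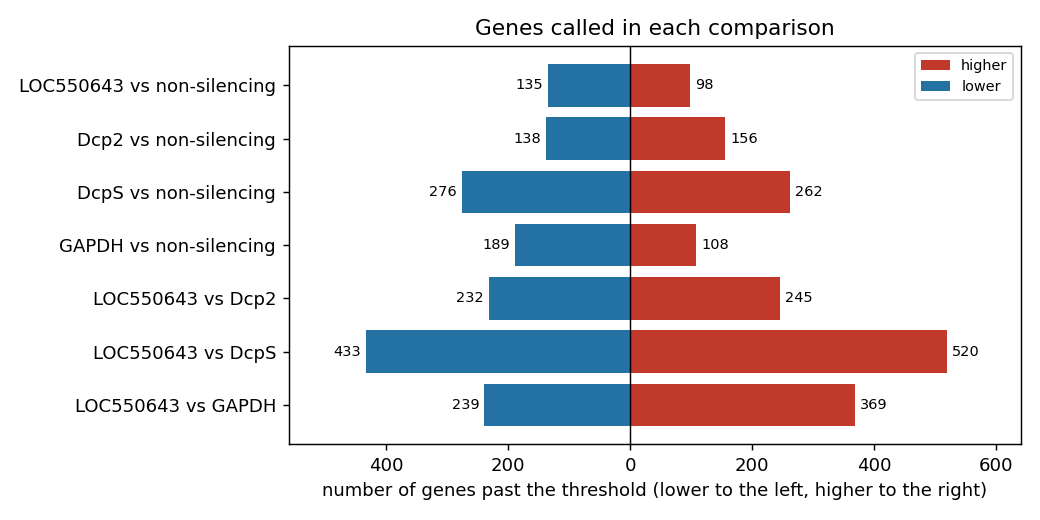
Number of genes called higher (right) and lower (left) in each comparison, named first group against second, on a linear scale of genes. The count was highest for LOC550643 against DcpS, with 520 genes higher and 433 lower.

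LOC550643 siRNA was set against the non-silencing siRNA to find the response to this pool, whose knockdown of LOC550643 was not analysed here. HABP4, which encodes an RNA-binding protein, rose by 1.25 log2 units (SE 0.09, limma adjusted p = 6.83e-06), TPM4, a tropomyosin, by 1.16, and G3BP2, a stress granule protein, by 1.10. NCS1, a neuronal calcium sensor, changed by -1.26 (SE 0.15, adjusted p = 0.000326), the myelin protein gene PLLP by -1.13, TMEM145 by -1.12, LIX1L by -1.10 and SUMF2 by -0.93. The formin DIAPH1 (-0.88), the cytosolic seryl-tRNA synthetase SARS1 (-0.95), the chromatin remodeler CHD1 (-0.99), SERTM1 (-0.89) and CDC123 (-0.87) were also lower. MED11, a Mediator subunit, rose by 0.95 and NOLC1, a nucleolar protein, by 0.90. The zinc finger genes ZNF267, ZNF567, ZNF766 and ZNF605 rose by 1.22, 1.00, 0.87 and 0.85, with OGFR at 0.90. HABP4, TPM4, G3BP2, MED11, NOLC1 and OGFR were also called higher with each of the other siRNAs. HABP4, for example, rose by 1.25 with Dcp2, 0.80 with DcpS and 1.32 with GAPDH siRNA. The changes of these genes were therefore not particular to LOC550643 siRNA. PLLP and TMEM145 were also called lower with DcpS (-0.57 and -0.67) and GAPDH siRNA (-1.02 and -0.72). LIX1L (-0.62) and DIAPH1 (-0.54) were called lower with DcpS siRNA too. ZNF267 was also called higher with Dcp2 (1.39) and DcpS siRNA (1.54), and ZNF766 with Dcp2 siRNA (0.89). The other genes named so far in this comparison were not called in the same direction with another siRNA. ZNF267 was not called without LOC550643 replicate 1 or 3 or non-silencing replicate 1 (limma adjusted p 0.0858 to 0.0988). ZNF567 was not called without LOC550643 replicate 2 or 3 or non-silencing replicate 1 or 2 (limma adjusted p 0.0676 to 0.148). ZNF766 was not called without LOC550643 replicate 1, 2 or 3 or non-silencing replicate 1 (limma adjusted p 0.0676 to 0.154). ZNF605 was not called without LOC550643 replicate 1, 2 or 3 or non-silencing replicate 2 or 3 (limma adjusted p 0.0709 to 0.130). OGFR was not called without LOC550643 replicate 1 or 3 (limma adjusted p 0.0515 to 0.0541).

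Among genes of RNA decay, EXOSC6, a subunit of the RNA exosome, fell by 0.66 log2 units and UPF2, a nonsense-mediated decay factor, rose by 0.64 with LOC550643 siRNA, while 0 of 12 measured decapping and P-body genes were called (0 adjusted over the list alone). Of 18 measured substrates of nonsense-mediated decay, 18 had positive changes with a median of 0.14 and 0 were called (0 adjusted over the list alone). That list was called with the preset correlation (adjusted p = 0.00257), but its adjusted p was 0.520 with an estimated correlation. Its members also followed the axis score within groups (median correlation 0.52). On that score the LOC550643 arrays averaged 1.32 and the non-silencing arrays -5.88. In the endoplasmic reticulum, 2 of 7 measured chaperone and unfolded protein response genes were lower, HYOU1 by -0.80 and SEL1L by -0.53. As a list they were not called by camera with an estimated correlation, where the smallest adjusted p of any list was 0.520. With the mean of its probe sets HYOU1 was at -0.44 and still called. Of 8 measured glycolysis genes, 8 had negative changes with a median of -0.14, and HK2 (-0.56) and GPI (-0.45) were called (2 adjusted over the list alone). This list was called with the preset correlation, but its adjusted p was 0.520 with an estimated correlation. The listed KRAB zinc finger genes had a median change of 0.25, with 16 of 20 positive and 0 called (3 adjusted over the list alone), and the adjusted p was 0.520 with an estimated correlation. The mitotic kinase gene CDK1 was at -0.62. UPF2 was not called without LOC550643 replicate 1, 2 or 3 or non-silencing replicate 1 (limma adjusted p 0.0558 to 0.120). SEL1L was not called without LOC550643 replicate 1, 2 or 3 or non-silencing replicate 1 or 2 (limma adjusted p 0.0613 to 0.171). CDK1 was not called without LOC550643 replicate 1 or 2 or non-silencing replicate 1, 2 or 3 (limma adjusted p 0.0502 to 0.160).

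In all, 98 genes were higher and 135 lower with LOC550643 siRNA (limma, adjusted p under 0.05), and the groups did not overlap for 17.0% of genes, where chance gives 10%. Here and below, that 10% is an average. How far a share departs from it by chance was not computed, and genes are not independent. Camera with an estimated correlation called 0 of 27 lists, with 2 at an unadjusted p under 0.05, against 4 lists called with the preset correlation. The count rested partly on single arrays, with 79 genes without non-silencing replicate 1, 114 and 122 and 126 without LOC550643 replicates 1, 2 and 3, and 53 when only these 6 arrays were fitted. CDK1, CHD1, GPI, OGFR, SARS1, SEL1L, UPF2, ZNF267, ZNF567, ZNF605 and ZNF766 were not called when only the 6 compared arrays were fitted (limma adjusted p 0.0506 to 0.186). CDK1 was not called after median centring (limma adjusted p 0.0558).

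**Figure D3:**
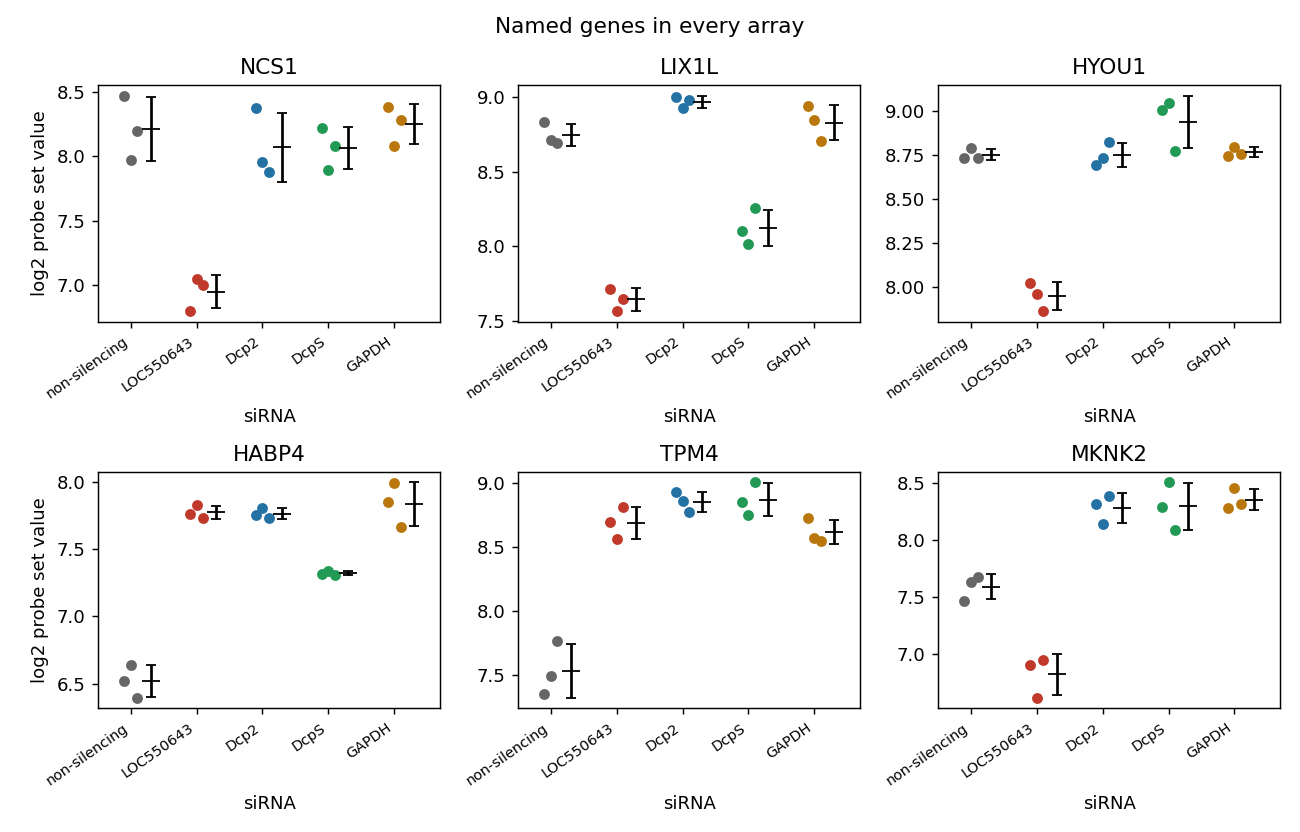
Log2 probe set values (vertical axes) of 6 genes named by the rule, by siRNA (horizontal axes); dots are single arrays and black bars the mean ± SD of 3. NCS1, LIX1L, HYOU1 and MKNK2 were lowest with LOC550643 siRNA, while HABP4 and TPM4 were lowest in the non-silencing arrays, at means of 6.52 and 7.54.

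Dcp2 siRNA, the functionally related comparison, was set against the same reference. GEM, a small GTPase, rose by 1.47 log2 units (SE 0.22, limma adjusted p = 0.00521), the transcription factor genes JUN by 1.42 and ATF3 by 1.41, RHOB by 1.33 and the phosphatase gene DUSP1 by 1.25. TPM4 (1.32), HABP4 (1.25), ZNF267 (1.39), ERRFI1 (1.14) and MYLIP (1.11) were also higher. Besides DCP2, the sphingosine phosphate lyase gene SGPL1 changed by -1.20 (SE 0.16, adjusted p = 0.00200), IRS4 by -1.18, IGFBP5 by -1.10, LINC00294 by -0.98, HTRA1 by -0.96 and RRP1B by -0.94. LMBRD2 (-0.93), ADAM23 (-0.92) and CEP19 (-0.87) were also lower. The 2 groups were unequally variable. The SDs of GEM, JUN and ATF3 were 0.60, 0.42 and 0.65 in non-silencing and 0.16, 0.08 and 0.06 in Dcp2 arrays. That of SGPL1 went the other way, at 0.16 and 0.31. The spread shared by all groups does not allow for such differences, so the SE of single genes may be too small. With the axis score as a covariate RHOB was at 0.85, MYLIP at 0.65, ERRFI1 at 0.61, IRS4 at -0.72, ADAM23 at -0.55, HTRA1 at -0.54 and CEP19 at -0.43. XRN1, the 5' exonuclease that acts after decapping, was at -0.43, and the antiapoptotic gene BCL2 was at -0.84. ATF3, DUSP1, ERRFI1, IRS4, HTRA1, ADAM23, CEP19 and XRN1 were not called without Dcp2 replicate 1, 2 or 3 or non-silencing replicate 1 or 2 (limma adjusted p 0.0523 to 0.216). ZNF267 and LMBRD2 were not called without Dcp2 replicate 1 or non-silencing replicate 1 (limma adjusted p 0.0522 to 0.0791). MYLIP was not called without Dcp2 replicate 1 or 3 or non-silencing replicate 1 (limma adjusted p 0.0577 to 0.0883). LINC00294 was not called without non-silencing replicate 1 (limma adjusted p 0.0548).

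Of 23 measured immediate early and other short-lived transcripts, 6 rose with Dcp2 siRNA and 0 fell (12 and 0 adjusted over the list alone), among them JUN, ATF3, KLF6 and DUSP1. The adjusted p of the list was 0.402 with an estimated correlation. These counts moved with single arrays, since 1 member was called without non-silencing replicate 1 or Dcp2 replicate 1, and 2 without non-silencing replicate 2 or Dcp2 replicate 2 or 3. The arrays also differed within groups along a shared axis, on which the Dcp2 arrays had a mean score of 7.77 and the non-silencing arrays -5.88, with replicate 1 of the latter at -18.8. With the axis score as a covariate, chosen after seeing the data, 4 members were called, and the changes of JUN, ATF3, DUSP1 and KLF6 were 0.91, 0.75, 0.66 and 0.47 instead of 1.42, 1.41, 1.25 and 0.98. The score was computed from genes that included these, so a real effect of Dcp2 siRNA on them is partly removed with it. The smaller changes cannot tell such an effect from a difference between arrays. Of 18 measured substrates of nonsense-mediated decay, 16 had positive changes with a median of 0.20, and only ATF3 was called (5 adjusted over the list alone), with an adjusted p of 0.402 with an estimated correlation. Of 18 measured mitotic genes, 17 had positive changes and 1, CDC20 at 0.43, was called (adjusted p = 0.413 with an estimated correlation). The substrates of nonsense-mediated decay and the mitotic genes also followed the shared axis, with median correlations of 0.52 and 0.57. KLF6 and CDC20 were not called without Dcp2 replicate 1, 2 or 3 or non-silencing replicate 1 or 2 (limma adjusted p 0.0736 to 0.185).

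With Dcp2 siRNA 156 genes were higher and 138 lower (limma), and groups did not overlap for 22.8% of genes against 10% by chance. Camera with an estimated correlation called 0 lists, with 3 at an unadjusted p under 0.05, against 5 with the preset correlation. The count was 41 without non-silencing replicate 1, 70 without non-silencing replicate 2, 63, 84 and 83 without Dcp2 replicates 1, 2 and 3, 39 when only the 6 arrays were fitted and 68 with the axis score as a covariate. JUN, GEM, RHOB, TPM4, HABP4, SGPL1, IGFBP5, RRP1B, BCL2 and DCP2 stayed called without each array in turn. ADAM23, ATF3, CDC20, CEP19, DUSP1, ERRFI1, GEM, HTRA1, KLF6, LMBRD2, MYLIP and XRN1 were not called when only the 6 compared arrays were fitted (limma adjusted p 0.0512 to 0.106). ADAM23, CDC20, CEP19, HTRA1, IRS4, KLF6, LMBRD2, XRN1 and ZNF267 were not called with the axis score as a covariate (limma adjusted p 0.0507 to 0.209). CDC20 was not called after quantile normalization (limma adjusted p 0.0595).

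DcpS siRNA gave the most calls against the reference. TPM4 rose by 1.34 log2 units (SE 0.11, limma adjusted p = 1.42e-05), TMEM31 by 1.296, the phosphoinositide phosphatase gene MTM1 by 1.15, NOLC1 by 1.02, the natriuretic peptide gene NPPC by 0.99, the ephrin gene EFNA3 by 0.98 and ACSL4, a long-chain fatty acid ligase, by 0.90. ZNF267 (1.54), CTSO (1.02) and EFNB2 (0.95) were also higher. SHISA2 changed by -1.47 (SE 0.11, adjusted p = 4.65e-06), the angiomotin gene AMOT by -1.42, the vesicle fusion ATPase gene NSF by -1.36, HCG11 by -1.19, GPR180 by -1.19 and ELMOD2 by -1.14. The RNA-binding protein gene TARDBP (-1.11), the proapoptotic gene PMAIP1 (-1.11), FAM241A (-1.05) and MAF (-1.03) were also lower. CTSO was not called without DcpS replicate 1, 2 or 3 or non-silencing replicate 2 or 3 (limma adjusted p 0.0510 to 0.170). EFNB2 was not called without DcpS replicate 2 or 3 or non-silencing replicate 1 or 2 (limma adjusted p 0.05003 to 0.0697). HCG11 was not called without non-silencing replicate 2 (limma adjusted p 0.0660).

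Of 18 measured G2 and M phase genes, 9 rose with DcpS siRNA and 0 fell (14 and 0 adjusted over the list alone). The motor gene KIF20A was at 0.86, the cyclin genes CCNA2, CCNF and CCNB1 at 0.77, 0.63 and 0.60, and 18 of 18 had positive changes with a median of 0.41. The list's adjusted p was 0.102 with an estimated correlation. Of 18 DNA replication genes, 16 had negative changes and MCM3, at -0.49, was called (adjusted p = 0.102 with an estimated correlation). Of 8 glycolysis genes, 8 had negative changes, and LDHA (-0.70) and PGAM1 (-0.61) were called (adjusted p = 0.117 with an estimated correlation). Among decapping and P-body genes the helicase gene DDX6 was at -0.56 and DCP1B at 0.44, and in the exosome EXOSC6 was at -0.54 and EXOSC7 at 0.32. BCL2 was at -0.66. CCNF was not called without DcpS replicate 2 (limma adjusted p 0.0674). PGAM1 was not called without DcpS replicate 1 or non-silencing replicate 3 (limma adjusted p 0.0770 to 0.0871). DCP1B was not called without DcpS replicate 2 or 3 (limma adjusted p 0.0530 to 0.0611). EXOSC7 was not called without DcpS replicate 1, 2 or 3 or non-silencing replicate 1, 2 or 3 (limma adjusted p 0.0693 to 0.138).

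In all, 262 genes were higher and 276 lower with DcpS siRNA (limma), with no overlap of groups for 18.5% of genes against 10% by chance. Camera with an estimated correlation called 0 lists, with 4 at an unadjusted p under 0.05, and 4 were called with the preset correlation. Without DcpS replicate 3 it called 2, the glycolysis and DNA replication lists, both with an adjusted p of 0.0481. The gene count was 276 without non-silencing replicate 2, 344 without DcpS replicate 2, 104 when only the 6 arrays were fitted and 982 with the axis score as a covariate. CCNF, CTSO, DCP1B, DCP2, DDX6, EFNB2, EXOSC6, EXOSC7, HCG11, KIF20A, LDHA and PGAM1 were not called when only the 6 compared arrays were fitted (limma adjusted p 0.0519 to 0.171).

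GAPDH siRNA, an unrelated comparison, gave higher HABP4 (1.32 log2 units, SE 0.09, limma adjusted p = 3.42e-06), CD68 (1.10), TPM4 (1.08), G3BP2 (1.02), the thioredoxin-binding gene TXNIP (0.97), EPDR1 (0.96), RHOB (0.91), MED11 (0.89), OGFR (0.88) and CBX6 (0.86). With the mean of their probe sets CBX6 was at 0.57 and ZEB2-AS1 at -0.54. CD68 was on the list of blood cell markers, of which 4 were measured and 1 was called. Besides GAPDH, the nucleotide hydrolase gene DNPH1 changed by -1.29 (SE 0.12, adjusted p = 2.48e-05), the topoisomerase gene TOP2B by -1.25, the ubiquitin protease gene USP25 by -1.08, HCG11 by -1.04, PLLP by -1.02, SYT17 by -1.02, the carbonic anhydrase gene CA2 by -1.02, ZEB2-AS1 by -0.998 and NCR3LG1 by -0.99. MYC was at -0.68 and HK2 at -0.57. Of 13 cholesterol synthesis genes, 12 had negative changes and 2, SQLE (-0.61) and IDI1 (-0.57), were called (5 adjusted over the list alone), with an adjusted p of 0.644 with an estimated correlation. Of this list 1 member was called without GAPDH replicate 2 or 3 or non-silencing replicate 2 or 3, and 6 with the axis score as a covariate. RHOB was not called without GAPDH replicate 1 or 3 or non-silencing replicate 1 or 2 (limma adjusted p 0.0870 to 0.157). HCG11 and ZEB2-AS1 were not called without GAPDH replicate 1, 2 or 3 or non-silencing replicate 1 or 2 (limma adjusted p 0.0641 to 0.181). IDI1 was not called without GAPDH replicate 2 or 3 or non-silencing replicate 2 or 3 (limma adjusted p 0.0781 to 0.131).

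With GAPDH siRNA 108 genes were higher and 189 lower (limma), and groups did not overlap for 17.3% of genes against 10% by chance. Median centring of the arrays moved the share of higher calls from 36.4% to 49.8%. Camera with an estimated correlation called 0 lists, with 0 at an unadjusted p under 0.05, and 2 with the preset correlation. The count was 139 without non-silencing replicate 2, 176 without non-silencing replicate 1, 146 and 182 without GAPDH replicates 1 and 3, 44 when only the 6 arrays were fitted and 479 with the axis score as a covariate. G3BP2, HCG11, IDI1, OGFR, RHOB, SQLE, TXNIP and ZEB2-AS1 were not called when only the 6 compared arrays were fitted (limma adjusted p 0.0549 to 0.139). RHOB and ZEB2-AS1 were not called after quantile normalization (limma adjusted p 0.0507 to 0.0509). ZEB2-AS1 was not called after median centring (limma adjusted p 0.0534). ZEB2-AS1 was not called with the mean of probe sets (limma adjusted p 0.0571).

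The specificity of the LOC550643 response was examined by setting its arrays directly against each comparison siRNA, without the non-silencing arrays. A difference between 2 siRNA groups can come from either of them, so these calls alone do not show a change with LOC550643 siRNA. SGPL1 averaged 6.82 with LOC550643, 6.79 with non-silencing and 5.58 with Dcp2 siRNA, whereas NCS1 averaged 6.95, 8.21 and 8.07. Likewise NSF averaged 8.04 with LOC550643, 7.98 with non-silencing and 6.61 with DcpS siRNA. TOP2B averaged 8.67 with LOC550643, 8.53 with non-silencing and 7.28 with GAPDH siRNA. Against Dcp2, the kinase gene MKNK2 was lower by -1.45 log2 units (SE 0.12, limma adjusted p = 1.12e-05), LIX1L by -1.33, CHD1 by -1.32, NCS1 by -1.12 and ATF3 by -1.11. DCP2 (2.21), SGPL1 (1.24), the Wnt receptor gene FZD6 (1.22), CA8 (1.14) and IRS4 (1.13) were higher. BCL2 was at 0.78, XRN1 at 0.50, EXOSC6 at -0.76, HYOU1 at -0.80 (-0.45 with the mean of its probe sets) and CDK1 at -0.84. Of 7 measured endoplasmic reticulum genes, 6 had negative changes with a median of -0.22 and only HYOU1 was called (4 lower adjusted over the list alone), with an adjusted p of 0.158 with an estimated correlation. ATF3 was not called without LOC550643 replicate 1 or 2 or Dcp2 replicate 1, 2 or 3 (limma adjusted p 0.0994 to 0.180). IRS4 was not called without LOC550643 replicate 1 or 2 or Dcp2 replicate 1 or 2 (limma adjusted p 0.0810 to 0.139). XRN1 was not called without LOC550643 replicate 1 or Dcp2 replicate 1 (limma adjusted p 0.0654 to 0.0783).

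Against DcpS, ARRDC4 was higher with LOC550643 siRNA by 1.71 log2 units (SE 0.17, limma adjusted p = 3.59e-05), GPR180 by 1.59, CDS1 by 1.56, FAM241A by 1.44 and NSF by 1.42. MKNK2 (-1.47), SUMF2 (-1.36), KRCC1 (-1.22), MYADM (-1.17) and HEG1 (-1.17) were lower. Of 18 mitotic genes, 11 were lower and 0 higher (12 and 0 adjusted over the list alone), among them CDK1 (-1.12), CCNF (-0.67) and KIF20A (-0.59). The adjusted p was 0.250 with an estimated correlation, and 4 members were called without LOC550643 replicate 1, 5 without LOC550643 replicate 2 or DcpS replicate 3, and 7 without DcpS replicate 1 or 2. With LOC550643, non-silencing and DcpS siRNA, CDK1 averaged 8.36, 8.98 and 9.48, CCNF 7.92, 7.96 and 8.59, and KIF20A 9.12, 8.86 and 9.72. The difference in these genes therefore also holds their rise with DcpS siRNA, and KIF20A was not below the reference with LOC550643 siRNA. Of 18 DNA replication genes, 4 were higher, MCM3 (0.56), CCNE1 (0.50), CCNE2 (0.60) and E2F1 (0.39), with an adjusted p of 0.120 with an estimated correlation. That count was 1 without DcpS replicate 1 and 2 without LOC550643 replicate 1. In the same order of groups MCM3 averaged 10.12, 10.05 and 9.56, CCNE1 7.75, 7.32 and 7.25, CCNE2 6.86, 6.69 and 6.27, and E2F1 8.30, 8.07 and 7.91. The difference in MCM3 thus lay mostly in the DcpS arrays. PMAIP1 was at 1.32 and HYOU1 at -0.99. EXOSC6, lower with both siRNAs than non-silencing and named here outside the rule, was at -0.12 between them and was not called (limma adjusted p = 0.554), and 0 of 18 measured exosome genes were called. KRCC1 was not called without LOC550643 replicate 1, 2 or 3 or DcpS replicate 1 or 3 (limma adjusted p 0.0646 to 0.177). KIF20A was not called without LOC550643 replicate 1, 2 or 3 or DcpS replicate 1, 2 or 3 (limma adjusted p 0.0545 to 0.127). CCNE1 was not called without LOC550643 replicate 1 or DcpS replicate 1 or 2 (limma adjusted p 0.0528 to 0.0694). CCNE2 was not called without LOC550643 replicate 3 or DcpS replicate 1 (limma adjusted p 0.0564 to 0.0595). E2F1 was not called without LOC550643 replicate 1 or 2 or DcpS replicate 1 or 3 (limma adjusted p 0.0564 to 0.0755). CCNE1, CCNE2 and E2F1 were not called when only the 6 compared arrays were fitted (limma adjusted p 0.0603 to 0.0861).

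Against GAPDH, BICC1 (1.41), TOP2B (1.39), GAPDH (1.24), USP25 (1.22) and FZD6 (1.20) were higher with LOC550643 siRNA, and MKNK2 (-1.53), NCS1 (-1.30), GDAP1 (-1.28), LIX1L (-1.19) and MYADM (-1.13) were lower. SARS1 was at -1.13, EXOSC6 at -0.70, HYOU1 at -0.82, CD68 at -0.90 and MYC at 0.91. SQLE (0.84) and IDI1 (0.58) of the 13 cholesterol synthesis genes were higher, with an adjusted p of 0.639 for the list with an estimated correlation. IDI1 was not called without LOC550643 replicate 3 or GAPDH replicate 2 (limma adjusted p 0.0588 to 0.0611).

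Calls numbered 245 higher and 232 lower against Dcp2, 520 and 433 against DcpS, and 369 and 239 against GAPDH (limma), with no overlap of groups for 22.4%, 21.9% and 21.6% of genes against 10% by chance. Camera with an estimated correlation called 0 lists in each, with 2, 4 and 0 at an unadjusted p under 0.05. Against GAPDH, median centring moved the share of higher calls from 60.7% to 49.7%. Without LOC550643 replicate 1 the counts were 149, 536 and 304; without LOC550643 replicate 2 they were 220, 564 and 388. The count against Dcp2 was 167, 262 and 251 without Dcp2 replicates 1, 2 and 3, that against DcpS was 569 without DcpS replicate 1, and that against GAPDH was 377 without GAPDH replicate 1. When only the 6 compared arrays were fitted, 446 genes were called against DcpS and 280 against GAPDH, and with the axis score as a covariate 1098 against GAPDH.

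Whether the LOC550643 response resembled that of Dcp2 more than those of the unrelated siRNAs was examined across genes, which are not independent replicates. The log2 changes against non-silencing had a Pearson r of 0.455 between LOC550643 and Dcp2, 0.335 with DcpS and 0.361 with GAPDH. Unchanged groups sharing the 3 control arrays gave a mean simulated r of 0.492, 0.493 and 0.474. The simulated arrays varied independently of one another, so the pairing counted between DcpS and non-silencing arrays was left out. The covariance exceeded the simulated one by 0.00762, 0.00301 and 0.00306, each within the simulated range. Genes called in both and higher in both numbered 28 with Dcp2, 35 with DcpS and 29 with GAPDH, where independent lists would share 1.03, 1.73 and 0.711, and genes lower in both numbered 5, 16 and 7, where they would share 1.25, 2.503 and 1.71. Simulated unchanged groups shared 0 calls in 100 draws, a value that leaves out real effects and so gives no measure of overlap where both groups respond. In each pair, the genes higher in both included the 15 that were higher than the reference with every siRNA. That part of the excess is not particular to any pair, and it may come from the shared control arrays. The DcpS and GAPDH groups were also used as separate controls, although their own responses then enter. With LOC550643 taken against GAPDH siRNA, r was -0.0398 with Dcp2 and -0.0320 with DcpS against non-silencing, and with LOC550643 taken against DcpS siRNA it was -0.0312 with GAPDH. With LOC550643 against non-silencing, r was 0.126 with Dcp2 against GAPDH siRNA and -0.0013 with DcpS against GAPDH siRNA. The differences between these correlations were not tested.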

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

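The tests of the zinc finger genes, of the array axis and of the genes low in the non-silencing arrays were chosen only after the results were seen, as were the genes named here outside the rule.

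Signal in probe sets with no gene name here lay outside the comparisons of named genes. Of 37519 such probe sets, limma called 76 with LOC550643 siRNA against non-silencing, 25 with Dcp2, 137 with DcpS and 72 with GAPDH.

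Zinc finger genes were frequent among the genes higher with LOC550643 siRNA than non-silencing, 20 of 98 calls (20.4%) against 3.42% of all genes tested (Fisher's exact test, adjusted p = 1.33e-09 over 14 tests, treating genes as independent, which related genes are not). Over all 509 such genes the median change was only 0.12 with LOC550643 siRNA, 0.05 with Dcp2, 0.03 with DcpS and 0.01 with GAPDH, and each lay above at least 99.8% of random sets matched on level. The random sets and lists used here were of genes drawn singly. Like Fisher's test they leave out correlation between related genes, so their spread may be too narrow and these shares are not p-values. With the score on the shared axis of differences within groups as a covariate, 19 of the 20 stayed called (median 0.67 against 0.72). So did 208 of all 233 genes called with LOC550643 siRNA. Calls were made against the spread within groups, which disfavours genes that follow an axis of that spread. The adjustment thus left the changes of the called genes, but cannot decide whether the axis bears on why zinc finger genes were frequent. The KRAB zinc finger list followed that axis (median r 0.48, above 100% of random lists). With the covariate the medians over all 509 became 0.09, -0.01, 0.02 and -0.0022. Low non-silencing arrays alone are argued against for the set but not for each gene: for the 8, 12 and 11 genes called without LOC550643 replicate 1, 2 and 3, the array left out lay 0.38 log2 units (mean of 3 medians, SD 0.05) above the other 3 siRNA groups, against 0.70 above non-silencing, while ZNF267 stood at -0.02. Cross-hybridization between related genes, off-target effects of the siRNA pool and a response to loss of NoBody may each account for it and were not tested.

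Arrays of 1 group differed along a shared axis that held 37.8% of the within-group variance. Among genes above the median level, SNRPG and ARRDC3 moved most at one end, where ATF3, DUSP1 and TIPARP also lay. F8A1 and FNDC10 moved most at the other end, where ASNS and PSAT1 also lay. The immediate early list had a median correlation of 0.61 with it, above 100% of random lists matched on level. Unequal levels of short-lived transcripts between samples could give this. However, the sign of the axis was set by this list, so its lying above the random lists and not below was fixed in advance. Its members above the median level also helped to define the axis, and the random lists were of genes drawn singly. Besides, 11 of 27 lists lay beyond the central 95% of such random lists, so the list does not single out that explanation. Brightness accounted for 0.390% of the variance of the slopes, which says nothing on brightness-dependent scaling, since the quantile normalization of the deposited values leaves little of it to see. Whether replicate number marks a batch cannot be told apart from chance with 3 numbers (exact permutation p = 0.113 over 7776 arrangements). Group means on the axis gave a permutation p of 0.410. The axis was chosen for variance within the real groups, which favours a large p, so this value cannot show that the groups are alike on it.

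Of the genes called in 1 direction against all 4 other groups, 15 were lower in the non-silencing arrays, among them TPM4, HABP4, G3BP2, MED11 and NOLC1, and 0 were higher (19 lower and 4 higher without non-silencing replicate 3, at most 1 higher without any other array, and 6 higher with the filter on dim genes). A single deviant array is argued against: each non-silencing array, left out while genes were chosen, lay below all 12 other arrays for at least 84.2% of the genes chosen, although only 5, 6 and 19 lower genes were chosen without replicates 1, 2 and 3. The axis is argued against for the size of the difference, with a median of -0.61 with it as a covariate and -0.67 without, but only 8 of the 15 were still set apart with that covariate. A response common to targeting siRNAs and an effect of the non-silencing siRNA itself may both account for them and stay open, since no untransfected arrays were analysed here.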

How the results depend on the processing

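The axis covariate, the counts of genes set apart and the counts of list members without an array were chosen after seeing the data; all other settings were planned. The targeted genes kept their calls in every setting, with DCP2 in the Dcp2 arrays between -1.88 and -1.75 and GAPDH in the GAPDH arrays between -1.30 and -1.09 when arrays were left out. Quantile normalization, median centring, limma's trend and other probe set rules moved no count of calls by over 1.5 times. Over all groups, 11 of 30 same-numbered pairs deviated together (r over 0.1) against 20 of 60 others, and 7 of 15 arrays correlated best with their own number; only DcpS and non-silencing met the rule for pairing. The replicate block gave 246, 436, 595 and 313 calls for LOC550643, Dcp2, DcpS and GAPDH against non-silencing. It gave 483, 990 and 659 for LOC550643 against Dcp2, DcpS and GAPDH, 2003 in the F test and 0 lists, and moved no count by over 1.5 times. It fitted an effect of each replicate number common to all groups, so a pairing of DcpS with non-silencing alone was not modelled. The pair of these groups with the highest r (0.613), replicate 1 of each, also had the lowest axis scores, -13.8 and -18.8. The filter on dim genes, which tests fewer genes, gave 403, 684 and 461 calls for LOC550643, Dcp2 and GAPDH against non-silencing, 750 for LOC550643 against Dcp2, and 112, 67, 234, 114 and 31 genes set apart in LOC550643, Dcp2, DcpS, GAPDH and non-silencing. Fits of the compared groups alone had fewer arrays for the spread and used only the spread of those groups. They gave 53, 39, 104 and 44 against non-silencing, and 446 and 280 for LOC550643 against DcpS and GAPDH. Groups differed in spread: the SD of the axis score was 11.4 in non-silencing, 7.5 in LOC550643, 2.2 in Dcp2, 9.8 in DcpS and 8.7 in GAPDH arrays. Whether fewer arrays or this difference lowered the counts was not tested. The axis covariate gave 68, 982 and 479 for Dcp2, DcpS and GAPDH against non-silencing, 1098 for LOC550643 against GAPDH, and 14, 234 and 112 genes set apart in Dcp2, DcpS and GAPDH; the cause was not tested. The preset correlation called 4, 5, 4 and 2 lists against non-silencing and 4, 4 and 5 in the direct comparisons. The DcpS and GAPDH groups as separate controls gave correlations of -0.0398 and 0.126 (Dcp2), -0.0320 and -0.0013 (DcpS), and -0.0312 and 0.0013 (GAPDH), of which -0.0013 and 0.0013 are 1 correlation with its sign turned.

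Leaving out each array gave 79 to 202, 41 to 393, 276 to 466 and 139 to 239 calls for LOC550643, Dcp2, DcpS and GAPDH against non-silencing, 149 to 468, 536 to 863 and 304 to 478 for LOC550643 against Dcp2, DcpS and GAPDH, and 1367 to 1783 in the F test. Lists called ranged from 0 to 2 for DcpS and were 0 elsewhere. Correlations ranged from 0.308 to 0.591 (Dcp2), 0.238 to 0.458 (DcpS) and 0.284 to 0.496 (GAPDH). Genes set apart ranged from 34 to 62, 12 to 41, 85 to 151, 49 to 68 and 5 to 23 in LOC550643, Dcp2, DcpS, GAPDH and non-silencing. Lower counts can follow from fewer samples alone, and the cause was not tested. Of 241 results of named genes, 92 were no longer called in fits of the compared groups alone, 22 with the axis covariate, 9 after median centring, 8 after quantile normalization and 7 with the block, ZNF605 in LOC550643 against non-silencing among them (limma adjusted p 0.0541). Of 1446 values of named genes without an array, 1042 stayed on their side of the threshold, 397 lost the call and 7 changed sign. The last were all GAPDH outside its own siRNA, uncalled throughout: in LOC550643 against non-silencing -0.07, -0.0333 and -0.0073 (range -0.07 to 0.0596; -0.002 with quantile normalization), in Dcp2 against non-silencing -0.0062 (to 0.0867), in LOC550643 against Dcp2 0.0177 and 0.0042 (from -0.1034), and against DcpS -0.0035. The signal over background is unknown here, so changes of dim genes are least certain.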

Other observations

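The comparison of each group with all 4 others, and the choice of the genes named here, were made after the data had been seen. With LOC550643 siRNA 69 genes stood apart from every other group, 59 lower and 10 higher. The kinase gene MKNK2 was at -1.303 log2 units from the mean of the others, the membrane protein gene MYADM was at -1.02, HEG1 at -0.998, the small nucleolar RNA host gene SNHG16 at -0.88 and CDK1 at -0.82. Of the 10 higher genes, ZNF587 (0.85), ZNF620 (0.73), ZNF614 (0.66), ZFP90 (0.64) and ZNF691 (0.45) were zinc finger genes, beside the ubiquitin ligase gene TRIM32 (0.61) and PRAME (0.52). MKNK2 was higher than non-silencing with the Dcp2, DcpS and GAPDH siRNAs, by 0.69, 0.70 and 0.76, and changed by -0.77 with LOC550643 siRNA. The count of 69 was 34 without LOC550643 replicate 1 or 2, 36 without non-silencing replicate 1, 45 without Dcp2 replicate 1 and 41 without Dcp2 replicate 3.

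Dcp2 siRNA set 31 genes apart, 4 higher and 27 lower, DcpS siRNA 151 (60 and 91), GAPDH siRNA 73 (7 and 66) and non-silencing 15 (0 and 15). With Dcp2 siRNA, SGPL1 was at -1.03, RRP1B at -0.96, ERO1B at -0.92 and RPIA, an enzyme of the pentose phosphate pathway, at -0.90. With DcpS siRNA, NSF was at -1.26, ARRDC4 at -1.21 and CDS1 at -1.16. With GAPDH siRNA, TOP2B was at -1.27, KIF20A at -1.15, AGFG1 at -1.11 and SLBP, the histone mRNA binding protein, at -1.08. The count for Dcp2 was 12, 15 and 18 without Dcp2 replicates 1, 2 and 3, 17 without LOC550643 replicate 1, and 13 and 15 without non-silencing replicates 1 and 2. For DcpS it was 85 without DcpS replicate 1 and 98 without non-silencing replicate 2. For non-silencing it was 5, 6 and 23 without its replicates 1, 2 and 3 (the last 19 lower and 4 higher), 7 without any 1 Dcp2 array, 6 without GAPDH replicate 1 and 9 without LOC550643 replicate 1 or 2. Among 99 random regroupings of the 15 arrays and the real one, only the real one reached the counts for LOC550643 (69, highest other 0), Dcp2 (31, highest other 23), DcpS (151, highest other 47) and GAPDH (73, highest other 71), 1 of 100 each, and 2 of 100 reached the count for non-silencing (15, highest other 29). The F test's 1815 genes were reached by 1 of 100, with 122 the highest other. Group names are arbitrary in a random regrouping, so its 5 groups were also pooled: of 495 random groups, 489 set 0 genes apart and the highest count was 71, above the 69 of LOC550643. Of 99 random regroupings, 1 had a group reaching the count of LOC550643, 2 that of Dcp2, 0 those of DcpS and GAPDH, and 5 that of non-silencing. The 15 genes of non-silencing were thus the count most often reached, by 5 of the 495 random groups. The count for Dcp2 ranged from 12 without Dcp2 replicate 1 to 41 without GAPDH replicate 3.

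For the comparisons of 2 groups, the 10 splits of 6 arrays are too few for a share under 0.05. The real split was the 1 of 10 that gave as many genes in each of the 7 comparisons (233, 294, 538, 297, 477, 953 and 608), and the highest other split gave 0. For gene lists, where the real count was 0, all 10 of 10 splits gave 0.

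Markers of keratinocytes (8 measured), hepatocytes (8), neurons (5) and fibroblasts (3) gave 0 calls by limma in each of the 7 comparisons. Of 4 measured blood cell markers only CD68 was called, higher with Dcp2 (0.47) and GAPDH (1.10) than non-silencing, higher with LOC550643 than DcpS (0.40) and lower with LOC550643 than GAPDH (-0.90). The call with Dcp2 ended without any 1 of the 6 arrays (limma adjusted p 0.0651 to 0.137), and that against DcpS without any 1 LOC550643 array or DcpS replicate 1 or 3 (0.0768 to 0.117). Both ended when only the compared arrays were fitted (0.110 and 0.0607), and the call with Dcp2 also with the axis score as a covariate (0.0952).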
